A study of Mus musculus with 6 samples.

How the data were processed

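Messenger RNA was sequenced from the hippocampus of wild-type mice and of mice lacking miR-301a, a microRNA whose gene lies within the host gene Ska2. The labels describe C57BL/6 animals aged 6 to 8 weeks. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was selected on beads, fragmented and reverse transcribed with random primers, and cDNA fragments of 250 to 300 bp were preferred in size selection. The libraries are named here by genotype and by the code in their titles: wild type 1-1, 2-1 and 2-2, and knockout 1-1, 2-2 and 3-1. What the code stands for is not stated, and nothing in the labels says that each library came from a separate animal. The p-values therefore measure the spread between these libraries, which may be partly technical.

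The deposited table held 54393 genes with 1 value per library. The table does not name the unit of these values. They were read as FPKM-like values as deposited by the authors, that is, read counts scaled by gene length and library depth, because their columns did not sum to a common total and 1 read was worth less in a longer gene. How the authors scaled them is not given in the sources used here. HISAT2 2.1.0, HTSeq, bcl2fastq and the mm10 build are named without roles, per the submitters' processing notes. The series' own design text names ANOVA and a different set of programs (BWA, TopHat and Cufflinks). Which of these made the table is not stated. Whether reads were counted by strand, and how reads that match several near-identical genes were treated, is also not given. The authors' deposited table further holds a log2 fold change, a p-value and an adjusted p-value per gene. The test is not named with them, and whether it was the ANOVA of the design text is not stated. Of its 30876 genes with a p-value, 64.9% had a value of exactly 1.

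Read depth was not given, and was approached from the low values. In genes with 160 nt or less of exonic sequence, 91.5% to 98.6% of the values above 0 were multiples of a single step divided by a whole number (up to 5 reads over an effective length of up to 15, within 0.2%), against a median of 0.568% to 1.14% for steps drawn at random. If the values are per kilobase and per 1e+06 reads, the steps correspond to depths (in units of 1e+06 reads) of 28.2, 20.1 and 20.3 in wild type 1-1, 2-1 and 2-2 and of 27.0, 16.9 and 19.7 in knockout 1-1, 2-2 and 3-1. These steps also give the largest number of reads a value can stand for, taking the full exonic length, and this upper limit is quoted where few reads lay behind a call. Exact read counts were not available, so no interval from counting was computed.

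Gene positions, exonic lengths and 3' UTRs came from GENCODE M21 on GRCm38, the assembly that mm10 denotes. All 54393 gene identifiers of the table were found in it, and 1057 genes of that annotation were not in the table. Positions are 1-based.

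The values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (linear model of genotype, empirical Bayes with a trend on mean level, two-sided) over the 14708 genes with a value of 1 or more in at least 3 of the 6 libraries. Fold changes are on this scale, which understates the change of genes with low values. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The plan written before the data were examined named a count-based test for a table of counts and this limma fit for a table of normalized values, and the second was used. Each group had 3 libraries, and all comparisons are knockout against wild type.

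Gene lists fixed before the data were examined (25 pathway lists and 19 lists of cell-type or region markers) were tested with limma's camera at a preset correlation of 0.01, adjusted over the 44 lists. Camera with an estimated correlation and fry were run beside it. For microRNA sites, the median log2 fold change of tested genes whose longest annotated 3' UTR held the heptamer TTGCACT, which pairs with nucleotides 2 to 8 of miR-301a-3p, was set against that of genes without the hexamer TGCACT, weighted to the same deciles of 3' UTR length. Site labels were permuted 100000 times within deciles (2000 times under each alternative), and other heptamers of the same base composition served as decoys where at least 300 tested genes held them. The site counts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

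Named genes followed a rule fixed beforehand: the targeted locus, up to 10 called genes in each direction whose groups did not overlap and whose mean was at least 50 reads, up to 4 members of each list by mean level, and called genes within 10 Mb of the locus. The 50-read part could not be applied without counts. All 16 called genes are named instead, and genes named beyond the rule are stated to have been chosen after their values were seen.

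The fit was tested on simulated data for the comparison of knockout with wild type, with the level and spread of the 14708 tested genes and 200 changed genes in each of 5 runs. It called 92.4% of the genes changed by a log2 fold of 1 and 100% of those changed by 2, with the right sign, and 4.18% of all calls were unchanged genes. In the same runs camera called 5 of 5 lists shifted by −0.2 and 0 of 5 unshifted lists. The simulated genes varied independently of each other, and changed genes were drawn from those with a mean log2(value + 1) above 2. The runs therefore did not test camera on lists whose genes vary together, nor the recovery of changed genes with low values. Spread was drawn equal in both groups, so false calls among genes at 0 in 1 group were not tested either. For 12741 simulated genes the weighted site comparison returned a mean of 0.0505 for a true shift of 0.05.

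Alternatives covered the pseudocount, the floor on low values, both readings of the title code as a block, and each library left out in turn. They also covered both wild-type libraries whose code begins with 2 averaged, removal of Xist and Y-linked genes, and a minimum fold change. Further ones were rescaling of the values, a robust fit, removal of genes under 200 nt, the list tests, and the definition of a seed site.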

Results

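Hippocampal poly(A) RNA from 3 wild-type and 3 miR-301a knockout libraries was compared to ask which transcripts differ when this microRNA is absent. miR-301a belongs to a family with miR-130a, miR-130b and miR-301b, whose members share a seed. The other members are encoded outside the miR-301a gene, so they remained encoded in these mice. Between 24101 and 25121 genes per library had a value above 0. Transcripts of the mitochondrial genome made up 16.1% to 22.8% of the summed values. Every library carried the X-inactivation transcript Xist at values of 57.8 to 84.0, while the Y-linked genes Ddx3y and Eif2s3y were listed at 0, so no library stood apart by sex. Correlations of log2 values across genes between pairs of libraries, where genes are not independent replicates, were similar within and between genotypes, for example 0.976 for wild type 2-1 and 2-2 and 0.978 for wild type 1-1 and knockout 3-1.

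The targeted locus was examined first. Mir301 (ENSMUSG00000065589.1, GRCm38 chromosome 11, 87113004 to 87113089) lies within Ska2, a gene for a subunit of a spindle and kinetochore complex (ENSMUSG00000020492.11, chromosome 11, 87109234 to 87124635). Mir301 was listed at 0 in all 6 libraries, wild type included, so its value does not check the genotype labels; poly(A) libraries are not built to hold mature microRNAs. Ska2 had values of 5.86 ± 0.195 (SD, n = 3) in wild type and 5.59 ± 0.503 (SD, n = 3) in knockout, a log2 fold change of −0.06 with limma (SE 0.09, adjusted p = 0.955). No called gene lay within 10 Mb of Mir301. The called genes Gm12338, Gm12208 and Pisd-ps1 lay farther away on chromosome 11, with Gm12338 the nearest at 75599763 to 75599954.

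Few transcripts differed between the genotypes. Of 14708 genes tested, 8 were higher and 8 lower in the knockout, and 841 had an unadjusted p under 0.05. Only 3 of the 16 were annotated as protein-coding: Amd2, Ide and Gm47283. The rest were annotated as pseudogenes, a microRNA, a ribosomal RNA and a miscellaneous RNA. The values of all 16 genes separated the groups without overlap, as did those of 1672 of the tested genes, or 11.4%, where chance alone gives 10% for 3 against 3. Even at the upper limit of reads, 10 of the 16 stood for fewer than 50 reads per library on average over all 6 libraries, and 8 over the libraries with a value above 0.

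The clearest difference was in Amd2, a copy of the gene for S-adenosylmethionine decarboxylase, an enzyme of polyamine synthesis (ENSMUSG00000063953.3, chromosome 10, 35708675 to 35711892). Its value rose from 0.277 ± 0.153 (SD, n = 3) in wild type to 8.49 ± 0.327 (SD, n = 3) in knockout, a ratio of 30.6 between the means (limma log2 fold change 2.90, SE 0.13, adjusted p = 0.00133). Amd1, the main gene for this enzyme and a possible source of shared reads, was at 46.6 ± 2.38 (SD, n = 3) and 46.3 ± 3.25 (SD, n = 3), a log2 fold change of −0.01. Ide, the insulin-degrading enzyme, which also cleaves amyloid beta (ENSMUSG00000056999.15, chromosome 19, 37268743 to 37337852), rose from 10.5 ± 1.53 to 23.4 ± 1.21 (SD, n = 3 each; limma log2 fold change 1.09, SE 0.11, adjusted p = 0.0288). Amd2 passed the threshold without each library in turn. Ide passed it only without wild type 1-1 (adjusted p = 0.0332) and missed it without wild type 2-1 or 2-2 or knockout 1-1, 2-2 or 3-1 (0.0761, 0.138, 0.113, 0.112 and 0.146), while its log2 fold change stayed between 0.98 and 1.17.

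The other calls with values above 0 in both genotypes were Pisd-ps1, Tmem181b-ps and Gm47283. Pisd-ps1, a transcribed copy related to the phosphatidylserine decarboxylase gene Pisd (ENSMUSG00000082286.10, chromosome 11, 3125904 to 3131004), rose from 34.5 ± 2.19 to 70.4 ± 5.77 (SD, n = 3 each; limma log2 fold change 1.01, SE 0.08, adjusted p = 0.0101). Tmem181b-ps, a transcribed copy of the transmembrane protein gene Tmem181a (ENSMUSG00000096780.7, chromosome 17, 6438524 to 6467022), fell from 55.2 ± 5.71 to 28.5 ± 2.72 (SD, n = 3 each; limma log2 fold change −0.93, SE 0.10, adjusted p = 0.0366). Gm47283, annotated on the Y chromosome (ENSMUSG00000096768.7, 90784738 to 90816464), had values of 3.42, 8.86 and 8.78 in wild type 1-1, 2-1 and 2-2 and of 64.7, 110.1 and 87.3 in knockout 1-1, 2-2 and 3-1 (limma log2 fold change 3.52, SE 0.34, adjusted p = 0.0243). Because Xist was present and Ddx3y and Eif2s3y were listed at 0 in every library, the values of Gm47283 cannot be read as Y-chromosome expression. How reads shared with related copies were placed is not given. Without any 1 library, Tmem181b-ps missed the threshold in all 6 fits (adjusted p = 0.0719, 0.139 and 0.217 without wild type 1-1, 2-1 and 2-2, and 0.124, 0.0792 and 0.146 without knockout 1-1, 2-2 and 3-1). Pisd-ps1 missed it without wild type 1-1, 2-1 or 2-2 (0.0569, 0.0528 and 0.0651), and Gm47283 without wild type 2-1 or 2-2 or knockout 2-2 or 3-1 (0.0791, 0.0703, 0.112 and 0.132).

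**Figure D1:**
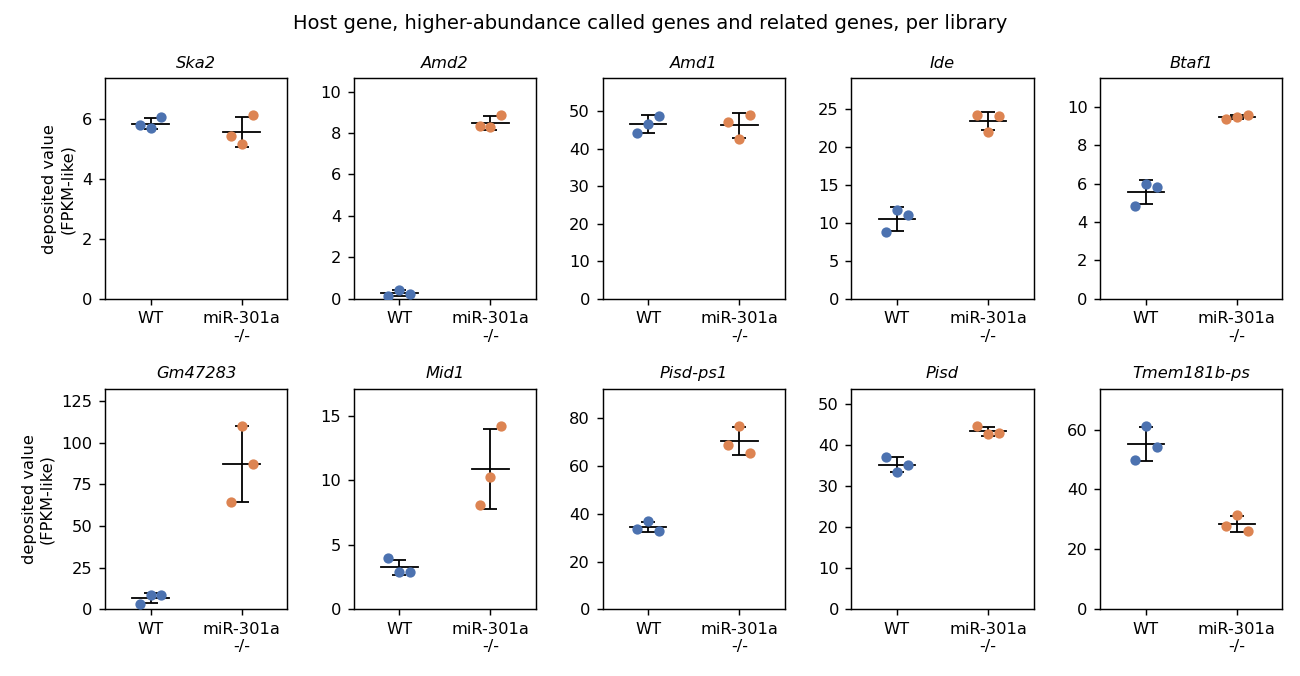
Deposited FPKM-like values (vertical axes, starting at 0) of the host gene Ska2, of called genes and of related genes in 3 wild-type (WT) and 3 miR-301a knockout libraries. Points are libraries, horizontal lines are means and bars are 1 SD; Amd2 lies between 0.143 and 0.444 in wild type and between 8.28 and 8.86 in knockout, while Ska2 and Amd1 overlap between genotypes, and Btaf1, Mid1 and Pisd did not pass the adjusted test.

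The remaining 11 calls were listed at 0 in all 3 libraries of 1 genotype, and no fold is given for them. The genotype at 0 shows no spread. Their limma p-values therefore rest on the spread of the other genotype and on the empirical Bayes step, and may be too small. Gm6741 and Gm12928, both processed pseudogenes, were at 2.65 to 4.46 and at 3.06 to 4.65 in the knockout libraries and at 0 in wild type (limma adjusted p = 0.0118 and 0.00873). Gm12751, Gm10241 and Gm43580, also processed pseudogenes, and the unprocessed pseudogene Gm26712 were at 0 in the knockout and reached 7.71, 2.77, 8.62 and 1.99 in wild type (limma adjusted p = 0.0146, 0.0118, 0.0326 and 0.0379). The other 5 had under 200 nt of exonic sequence. Gm12208 and Gm27348 were seen only in knockout libraries (7.26 to 16.9 and 5.08 to 7.40), and Gm12338, Gm22625 and n-R5s8 only in wild-type libraries (15.8 to 35.6, 9.96 to 17.8 and 4.44 to 14.1). Of these, Gm12208, Gm27348, Gm22625 and n-R5s8 stood for at most 38.8, 22.7, 38.7 and 21.8 reads on average in the 3 libraries where each was seen. Gm27348, Gm12338 and Gm22625 passed limma without each library in turn. Leaving out a library of the genotype at 0 left their log2 fold changes the same, so those fits add no test of their values. Gm12208 was lost without wild type 2-1 or 2-2 (adjusted p = 0.0573 and 0.0538), Gm12928 also without knockout 2-2 (0.0573, 0.0538 and 0.0554), and Gm6741 without wild type 1-1, 2-1 or 2-2 or knockout 2-2 (0.0621, 0.0791, 0.0703 and 0.0792). In limma n-R5s8 passed only without wild type 1-1 or 2-2 and otherwise had adjusted p = 0.263 without wild type 2-1 and 0.124, 0.166 and 0.16 without knockout 1-1, 2-2 and 3-1. Gm12751 and Gm43580 passed only without wild type 1-1; without wild type 2-1, wild type 2-2, knockout 1-1, 2-2 and 3-1 Gm12751 had 0.0987, 0.0703, 0.0592, 0.0853 and 0.0874 and Gm43580 0.0573, 0.204, 0.113, 0.147 and 0.146 (limma adjusted p). Gm10241 passed only without knockout 1-1, with 0.0719, 0.0987 and 0.0538 without wild type 1-1, 2-1 and 2-2 and 0.0792 and 0.066 without knockout 2-2 and 3-1 (limma adjusted p). Gm26712 was lost in every such fit, with 0.0719, 0.334 and 0.287 without wild type 1-1, 2-1 and 2-2 and 0.124, 0.163 and 0.155 without knockout 1-1, 2-2 and 3-1 (limma adjusted p).

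The authors' deposited table gave 8 genes an adjusted p under 0.05, all of them higher in the knockout. Of these, 5 were also called here, namely Amd2, Gm47283, Gm6741, Gm12928 and Ide. In the authors' deposited table Mid1 and G530011O06Rik also passed (adjusted p = 0.000751 and 0.000252), as did 4921516A02Rik, whose values were too low to be tested here. Mid1, a ubiquitin ligase gene on the X chromosome, had values of 3.27 ± 0.593 and 10.9 ± 3.10 (SD, n = 3 each), a limma log2 fold change of 1.45 with an adjusted p of 0.108. None of the 8 lower genes called here passed in the authors' deposited table.

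Which genes passed the threshold changed when single libraries were left out. Such a change need not come from the library itself, since fewer libraries remained to estimate the spread and the adjustment over all genes changed. Gm12208 and Gm12928 were at 0 in every wild-type library and kept the same log2 fold change without any 1 of them. Their limma adjusted p still ran from 0.0414 without wild type 1-1 to 0.0573 without wild type 2-1. No called gene changed its direction, but without 1 library this could not happen, since the groups of all 16 did not overlap. The 16 calls became 13, 4 and 6 without wild type 1-1, 2-1 and 2-2 (11, 4 and 5 of them shared with the 16) and 17, 6 and 11 without knockout 1-1, 2-2 and 3-1 (10, 6 and 8 shared). With the floor applied again to the 5 libraries left, they were 2 to 5. With all tested genes kept, the log2 fold changes without 1 library ran from −0.998 to −0.849 for Tmem181b-ps, from 0.94 to 1.06 for Pisd-ps1 and from 3.14 to 3.72 for Gm47283. When values of all libraries were rescaled by the median of their ratios, 8 higher and 8 lower genes were again called, all of them shared with the calls above.

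Gene lists moved little in size, and no list member was called over all genes. Ribosomal protein genes had the smallest camera p-value: 24 of 25 cytosolic ribosomal protein genes were lower in the knockout, with a median log2 fold change of −0.16 (camera adjusted p = 2.81e-09 at the preset correlation). The estimated-correlation test gave adjusted p = 0.892 for this list (unadjusted p = 0.0693), and fry gave adjusted p = 0.49 (unadjusted p = 0.018). None of the 25 passed when adjusted over the list alone. Rps21, for example, was at 1006 ± 31.7 and 765.3 ± 94.8 (SD, n = 3 each), and Rplp1 at 1607 ± 111.4 and 1441 ± 83.8 (SD, n = 3 each). Without each library in turn the list stayed lower, with medians of −0.19 to −0.12, and was called each time at the preset correlation.

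Activity-related and clock genes were lower on balance at the preset correlation. Of 22 immediate early genes, which respond quickly to neuronal activity, 16 were lower (median −0.13, camera adjusted p = 0.00386; adjusted p = 0.892 with an estimated correlation). Arc, needed for synaptic plasticity, was at 48.0 ± 8.02 and 35.1 ± 9.01 (SD, n = 3 each), Junb at 44.7 ± 4.93 and 37.0 ± 2.66 (SD, n = 3 each), and Egr3 at 40.6 in both genotypes. Of 18 circadian clock genes, 14 were lower (median −0.11, camera adjusted p = 0.0377; adjusted p = 0.892 with an estimated correlation), with Dbp at 45.5 ± 1.48 and 40.1 ± 4.17 (SD, n = 3 each). The immediate early list lost its call without wild type 1-1 (adjusted p = 0.0946, median −0.09), and its median was −0.26 without wild type 2-1 and −0.21 without knockout 2-2. The clock list lost its call without wild type 2-1 or 2-2 or knockout 1-1 (0.133, 0.140 and 0.563), with a median of −0.05 without knockout 1-1.

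Markers of hippocampal subfields differed in opposite directions. All 12 CA3 pyramidal neuron markers were higher in the knockout (median 0.19, camera adjusted p = 0.00386), while 7 of 9 CA1 markers were lower (median −0.33, camera adjusted p = 0.0377); both gave adjusted p = 0.892 with an estimated correlation. Cpne4, a CA3 marker, was at 38.9 ± 4.41 and 54.1 ± 14.5 (SD, n = 3 each), and Mpped1, a CA1 marker, at 83.8 ± 5.21 and 63.8 ± 9.73 (SD, n = 3 each). Wfs1, another CA1 marker, was at 47.9 ± 16.1 and 45.8 ± 7.99. Knockout 1-1 held the extreme medians of both lists, 0.48 and −0.44 from the wild-type mean on the log2 scale. The medians of erythroid and ependymal markers were also highest in this library, 0.99 and 0.65 from the wild-type mean. Ttr, a choroid plexus transcript, was at 12.2, 10.7 and 2.74 in knockout 1-1, 2-2 and 3-1 against 1.41 to 2.57 in wild type. Without knockout 1-1 the CA3 and CA1 lists were no longer called (adjusted p = 0.234 and 0.0646), and their medians were 0.07 and −0.22. Without knockout 2-2 the CA3 median was 0.29. The CA3 list also lost its call without wild type 2-1 (0.0953), and the CA1 list without wild type 1-1 or 2-2 or knockout 2-2 (0.18, 0.0572 and 0.204). Endothelial markers were higher for 11 of 14 genes (median 0.13, camera adjusted p = 0.0377; adjusted p = 0.892 with an estimated correlation), with Slc2a1 at means of 26.4 and 30.3 (n = 3 each), and lost the call without wild type 2-1 or 2-2 or knockout 1-1 or 3-1 (adjusted p = 0.66, 0.13, 0.0899 and 0.32). Their median was 0.01 without wild type 2-1, 0.08 without knockout 3-1 and 0.24 without wild type 1-1.

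**Figure D2:**
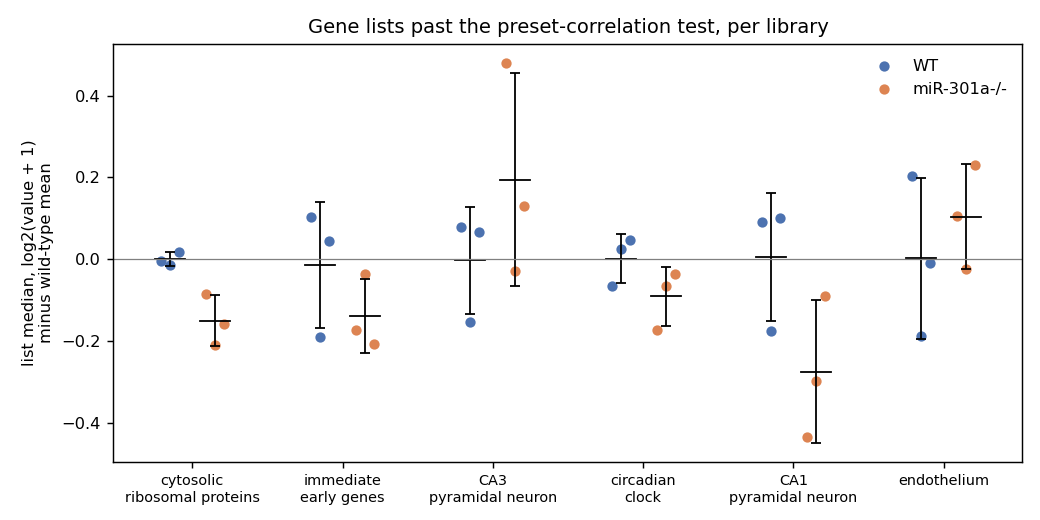
Median over each list's tested genes of log2(value + 1) minus the wild-type mean (vertical axis), for the 6 lists called by camera at the preset correlation. Points are libraries (3 wild-type, WT, and 3 knockout), horizontal lines are means and bars are 1 SD; the groups lie apart for ribosomal protein genes and overlap for the other 5 lists, and none of the 6 passed with an estimated correlation.

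The other 38 lists had camera adjusted p-values from 0.0728 to 0.892. The list of reported or predicted targets of the miR-301a family had a median log2 fold change of 0.01 over 16 tested genes, 9 higher and 7 lower (camera adjusted p = 0.892). Synaptic vesicle release genes (median 0.01, 11 higher and 11 lower) and glutamate receptor genes (median 0.00494, 11 higher and 11 lower) were balanced in direction. Of 21 postsynaptic density genes, 15 were higher (median 0.07, camera adjusted p = 0.0796). Without 1 library the median of the postsynaptic list ran from 0.04 to 0.11. Camera called it in 2 of these fits, and its adjusted p reached 0.639 without wild type 2-1. Among 18 glucocorticoid response genes, Pdk4, an inhibitor of pyruvate oxidation, and Hif3a, a hypoxia-inducible factor subunit, passed when adjusted over the list alone (limma adjusted p = 0.0115 and 0.0177) but not over all genes (0.277 and 0.51). Pdk4 was at 2.91 ± 0.111 and 5.42 ± 0.847, and Hif3a at 1.31 ± 0.204 and 2.62 ± 0.313 (SD, n = 3 each); the list itself did not pass (camera adjusted p = 0.277).

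Transcripts carrying sites for miR-301a were compared next, since loss of a microRNA predicts a rise of the messages it pairs with. The 1610 tested genes with the heptamer TTGCACT in the 3' UTR had a median log2 fold change higher by 0.00691 than that of 7961 genes without the hexamer, at the same 3' UTR lengths (two-sided permutation p = 0.108). Without 1 library this difference was 0.00426 to 0.0127, with a permutation p under 0.05 except without wild type 1-1 or knockout 1-1. Against all other genes with a 3' UTR the difference was 0.00519, and 65 of 333 decoy heptamers gave a difference at least as high. For the 331 genes with the longer 8-mer TTGCACTA, an alternative fixed beforehand, the difference was 0.0277 (permutation p = 0.001, from 2000 permutations), and 0.0113 without wild type 1-1. Genes are not independent replicates, so these p-values do not measure the spread between libraries. Camera over the heptamer genes gave an unadjusted p of 0.0133 toward higher values at the preset correlation and 0.0381 with an estimated correlation, without matching on 3' UTR length. Without weighting by 3' UTR length the heptamer difference was 0.0348 (permutation p = 0.0005, the smallest that 2000 permutations can give).

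**Figure D3:**
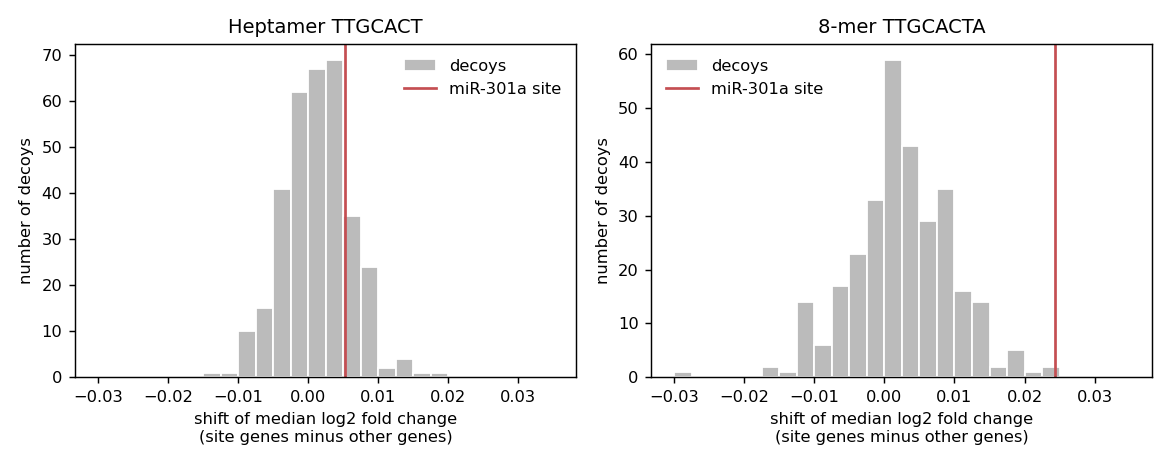
Number of decoy sites (vertical axes) by the shift in median log2 fold change of genes that hold them over other genes with a 3' UTR (horizontal axes), at matched 3' UTR length. Left, heptamers with the bases of TTGCACT, where 65 of 333 decoys lie at or above the red line of the miR-301a site at 0.00519; right, the same heptamers followed by A, where the miR-301a 8-mer at 0.0243 lies at the upper end of 303 decoys held by 100 or more genes.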

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

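Alternatives chosen only after seeing the data were the rescalings, the robust fit, the removal of genes under 200 nt, the floor of 5, and the choice of tested genes when a library was left out. No alternative reversed the direction of a called gene or list. For called genes the direction was fixed when a library was left out, since their groups did not overlap. Counts of calls kept within 1.5 times of 8 higher and 8 lower genes at a pseudocount of 0.1 (12 and 7) and after the 3 rescalings. The same held in the robust fit, without Xist and Y-linked genes, and at a log2 fold change of at least 1. A pseudocount of 0.01 left 4 higher and 2 lower genes, no floor on low values 2 and 2, and averaging wild type 2-1 with 2-2 left 2 and 2. Lower genes numbered 5 without genes under 200 nt and 3 at a floor of 5, where fewer genes were tested. Leaving out 1 library gave 2 to 9 higher and 2 to 8 lower genes when the 14708 tested genes were kept, and 0 to 5 and 0 to 3 when the floor was applied again, a step that by its construction removes a gene at 0 in 1 group when the library left out belongs to the other group. Keeping the gene set was decided after both had been seen. Of the 16 called genes, 4 passed in each of the 6 leave-one-out fits (Amd2, Gm12338, Gm22625 and Gm27348), and Tmem181b-ps and Gm26712 in none. Of these 4, only Amd2 passed in the authors' deposited table. There Gm12338, Gm22625 and Gm27348 had unadjusted p = 0.000889, 0.149 and 0.424, from a test that is not named with them. Here Gm12338, Gm22625 and Gm27348 were at 0 in 1 genotype, so the fits without a library of that genotype add no test of their values.

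Both groups have libraries coded 1-1 and 2-2, but the labels do not say that a code pairs libraries. Deviations from the group means correlated at −0.0986 and −0.0606 across genes for these pairs, so the codes were not used to pair samples. With the full code as a replicate block, 1 residual degree of freedom was left and 0 higher and 0 lower genes were called (611 at an unadjusted p under 0.05). With the first number of the code as the block there were 6 higher and 2 lower genes.

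Of 6 lists called, 0 passed with an estimated correlation and 0 with fry, and 3 to 12 were called without 1 library. The site difference of 0.00691 moved to 0.00426 to 0.0127 without 1 library, to 0.011 with the first number as a replicate block, to 0.00785 with the 3' UTRs of every transcript joined, to 0.0277 for the 8-mer and to 0.0348 without weighting; it had a permutation p under 0.05 in each of these except without wild type 1-1 or knockout 1-1. After rescaling by the median of ratios it was 0.00689 (permutation p = 0.117). The cause was not tested in any of these cases, apart from the tested gene sets named. Alternatives named before the data were examined that need counts (other size factors, a Wald test, voom, a robust quasi-likelihood fit and count filters) and a sex term were not run, for want of counts and because sex did not vary.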

Other observations

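Tests chosen only after the result was seen were those on the Pisd and Tmem181 families, the chromosome 19 segment, clustering on the map, the short genes, the decoys for the risen genes, and the regroupings of libraries for gene and list counts. The others were fixed before their results were seen.

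Several genes with small unadjusted p-values did not pass over all genes, and were chosen after their values were seen for their place near a called gene or near each other. Btaf1, which encodes a regulator of the TATA-binding protein (chromosome 19, 36926079 to 37012752), was at 5.56 ± 0.626 and 9.48 ± 0.0908 (SD, n = 3 each; limma adjusted p = 0.116), and Fgfbp3 next to it at 3.88 ± 0.431 and 6.48 ± 1.12 (SD, n = 3 each; limma adjusted p = 0.565). Prr14l, next to Pisd on chromosome 5, which was not called either, was at 7.89 ± 0.281 and 12.4 ± 1.22 (SD, n = 3 each; limma adjusted p = 0.188). Dynlt1b, a dynein light chain gene next to Tmem181b-ps on chromosome 17, was at 18.3 ± 1.63 and 9.24 ± 1.70 (SD, n = 3 each; limma adjusted p = 0.142). Mid1 and G530011O06Rik overlap on the X chromosome, and G530011O06Rik was at 0.266 ± 0.0231 and 2.12 ± 0.831 (SD, n = 3 each; limma adjusted p = 0.237). Mid1-ps1, annotated near Gm47283 on the Y chromosome (90753057 to 90763485), was at 0.362 ± 0.106 and 1.31 ± 0.289 (SD, n = 3 each, limma adjusted p = 0.52).

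Markers of tissue next to the hippocampus varied between libraries. Ttr, a choroid plexus transcript, was at 1.68, 1.41 and 2.57 in wild type 1-1, 2-1 and 2-2 and at 12.2, 10.7 and 2.74 in knockout 1-1, 2-2 and 3-1 (limma adjusted p = 0.832), and 7 of 7 tested choroid plexus markers were higher (camera adjusted p = 0.0833). All 14 oligodendrocyte markers were lower (median −0.16, camera adjusted p = 0.104), with the extreme library medians 0.32 in wild type 2-2 and −0.52 in knockout 2-2. Without 1 library the median of this list ran from −0.32 to 0.03, so its direction depended on single libraries.

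Called genes and their neighbours were first weighed as a question of where reads were placed. If reads had only moved between copies, the summed length-weighted value of a family would stay level. It was 1.15 times as high in the knockout for Amd1 with Amd2, which argues against reads moved from Amd1 to Amd2. It was 1.43 times as high for Pisd, Pisd-ps1 and Pisd-ps2, and 0.644 times for Tmem181a, Tmem181b-ps and Tmem181c-ps. In each case the 3 knockout libraries lay beyond all 3 wild-type libraries. Further copies named for these sums, Pisd-ps3 and Tmem181d, are not in the table under those names, so reads exchanged with copies outside the sums stay open for Pisd and Tmem181a. Among 28 genes of 200 nt or more with an unadjusted p under 0.001 there were 3 pairs within 500 kb, a number reached by 78 of 10000 random sets. Without genes that overlap each other, as Mid1 and G530011O06Rik do, 2 pairs were left, reached by 431 of 10000. The count was made after such neighbours had been seen, so whether changed genes are placed independently of each other is left open. A DNA difference between the mouse lines over a short segment around Ide is also left open. Of 4 tested neighbours within 250 kb, 0 had a p under 0.05 with its sign, but this window was chosen after the values were seen and leaves out Btaf1 and Fgfbp3, 256 kb and 349.1 kb away. Up to the distance of Fgfbp3 there were 2 of 6. Between them and Ide lie Cpeb3, with a log2 fold change of 0.17 (SE 0.08), and March5, with −0.07 (SE 0.06). No genomic DNA was analysed here.

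Calls in genes under 200 nt were weighed as an effect of few reads. Of the 5 such calls, 4 stood for fewer than 50 reads on average even at the upper limit, both over all 6 libraries and over the 3 with a value above 0, a value that goes with the explanation that a few reads over a very short effective length give large values. Gm12338, at up to 110.2 reads in the libraries where it was seen, is not settled by this. Few reads were not confined to genes under 200 nt. Among longer calls, Gm26712, Gm10241, Gm43580 and Gm12928 stood for at most 8.57, 16.25, 35.2 and 43.8 reads on average where seen. Gm6741 and Gm12751 stood for at most 56.7 and 50.9, and the other longer calls for more. By this upper limit few reads do not set the short calls apart, but it takes the full exonic length and is looser for short genes. At the smallest effective length that gave whole reads, Gm12208 stood for 2, 2 and 1 reads in knockout 1-1, 2-2 and 3-1. Gm27348 then stood for 2, 1 and 1 there. In wild type 1-1, 2-1 and 2-2, n-R5s8 stood for 7, 8 and 16, Gm12338 for 8, 10 and 13, and Gm22625 for 45, 18 and 20. These are smallest readings, and the true counts may be higher. No biological explanation was tested.

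Lower ribosomal protein genes were weighed against a trend with length and level. Across 12811 protein-coding genes, which are not independent, log2 fold change and exonic length correlated at a Spearman rho of 0.252, shorter genes being lower in the knockout. The list's median of −0.16 lay below each of 10000 lists matched on length and level, whose central 95% ran from −0.08 to −0.02. The matched genes were drawn independently, while the ribosomal list had an estimated correlation of 0.322, so this range lacks the list's shared variation. The test therefore cannot tell whether the trend accounts for a part or all of the difference. No single library decided it, since the highest median without 1 library was −0.12. Genotype, RNA quality and time of dissection stay open, and the estimated correlation gave an unadjusted p of 0.0693.

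One hypothesis was that genes that rose at an unadjusted p under 0.001 include direct miR-301a targets. Of 9 such genes with an annotated 3' UTR and at least 200 nt, 6 held the heptamer (Mid1, Gpcpd1, Btaf1, Prr14l, Pdk4 and Nhsl2; 66.7%, exact 95% interval 29.9 to 92.5), against 12.6% of other tested genes (one-sided Fisher's exact p = 0.000241), and 0 of 6 genes that fell at that threshold. Of 333 decoy heptamers, 0 were held by as many of the 9 genes, though ACTTGTC, CACTTGT, CTTTGAC and TTTGCAC were each held by 5. From 3' UTR length alone 1.44 was predicted. Base composition and 3' UTR length alone are therefore argued against, but by a narrow margin. The share of 6 of 9 goes with loss of repression. It rests on few genes, 3 of which (Mid1, Btaf1 and Prr14l) lie beside other genes with small p-values. Of the 3 called genes with a 3' UTR, 0 held the heptamer. At an unadjusted p under 0.01 the share of risen genes was 12 of 47, where 3' UTR length predicted 8.19. Among genes that fell at that threshold it was 6 of 69, where 3' UTR length predicted 5.47.

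A second hypothesis was a small rise of all messages with the 8-mer site. Their shift over other genes with a 3' UTR, 0.0243, lay above 0.0174, the upper end of the central 95% of 303 decoys, although the highest decoy, held by 144 genes, came to 0.0243 as well at this rounding. The lowest decoy, GCTATCT followed by A and held by 171 genes, came to −0.0289, larger in size. The place of the miR-301a 8-mer above the central 95% argues against base composition and 3' UTR length alone. Single decoys still reached shifts of this size in both directions. A weak loss of repression may be present but is not shown. Against genes without the hexamer the shift was 0.0277 and fell to 0.0113 without wild type 1-1. Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05; 1 of them, the real one, gave a shift this large, and the highest of the others was 0.0164. For the heptamer 3 of the 10 splits gave a shift as large, with 0.00691 for the real one and 0.0107 for the highest other.

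Another hypothesis was that DNA of the targeting strain flanks the miR-301a locus. Within 10 Mb of Mir301, 8.12% of 197 tested genes had an unadjusted p under 0.05, against 5.69% elsewhere (one-sided Fisher's exact p = 0.0995; odds ratio 1.47, exact 95% interval 0.817 to 2.46). The interval holds both an equal share and an excess above 1.5, so the test leaves this open. Of 16 tested genes in the list of neighbours of the locus, 14 were higher (median 0.06). Camera gave an unadjusted p of 0.022 (adjusted p = 0.088), and 0.07 with an estimated correlation (adjusted p = 0.892). Fry, which tests a list against no change rather than against other genes, gave 0.0223 (adjusted p = 0.49). These values do not settle it either.

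The 10 splits are likewise too few to give a share under 0.05 for the counts of calls. In the real split both directions held 8 genes; the larger direction reached at most 7 and the smaller at most 4 in the other splits, so that 1 split, the real one, reached each count. At an unadjusted p under 0.05 the real split had 841 genes, and 4 of the others had more (862, 896, 934 and 974). For gene lists at the preset correlation, 7 of the 10 splits called 6 or more, and 1 of the others called 21. That split set wild type 1-1 with knockout 2-2 and 3-1 against the rest. The number of lists called at the preset correlation therefore did not set the genotypes apart from other groupings. Single lists were not followed through the splits.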
